A study of Homo sapiens with 8 samples.

How the data were processed

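RNA was sequenced from ZR-75-1 cells, an established estrogen receptor positive human breast cancer line. Per the labels' protocols, the cells were kept for 72 h in steroid-depleted medium and then treated for 4 h with 10 nM estradiol (E2) or with 10 nM E2 and 10 nM dihydrotestosterone (DHT), a potent androgen, together. There were 4 libraries per treatment and no arm without hormone, so E2+DHT can be compared with E2 and the effect of E2 itself cannot be measured. Per the labels' protocols, total RNA went into a stranded total RNA library kit and was read as paired ends.

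The treatment labels conflict. In 4 of the 8 records the title and the library name given as the description name different treatments. Groups and replicate numbers were taken from the library name, which also heads that library's column of values. The grouping by record titles, and the 4 records on which both labels agree, were kept as alternatives. The passage field follows the titles. Read with the titles' own replicate numbers, numbers 1 to 4 have passages 8, 9, 10 and 11 in both treatments, so that equal numbers share a passage. Whether equal numbers mark pairs is not stated. Read record by record under the library names, passages 8 and 10 fall to E2 and passages 9 and 11 to E2+DHT. Under this reading each passage has 1 treatment only, so that passage and treatment cannot be separated, except for a steady trend over the passages. The labels do not say whether the replicates were separate cultures. Where they were not, the p-values measure only the spread between these samples.

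The authors deposited RPKM values (reads scaled by exon length and by the reads of the library) in a single table of 57773 genes, 27594 of them above 0 in at least 1 library. Per the submitters' processing notes the genome build was hg19, and the coordinates given here are those of the deposited table on that build. The aligner, the counting tool and its use of strand, and the annotation version are not given in the sources used here. Because a value of each gene moves in steps of 1 read, whole reads could be recovered from the RPKM values. For all 27594 expressed genes (100% at a tolerance of 0.0001 reads) the 8 values could be written as whole reads divided by the same exon length and by 1 denominator per library. The shortest length that gave whole reads was taken. For genes with reads in few libraries such a length is easily found, and their recovered reads may be too low. These denominators, the library sizes behind the scaling, were 31913885, 25476963, 19955045 and 20474595 reads for E2 replicates 1 to 4. They were 34616639, 19599217, 34474096 and 31906137 reads for E2+DHT replicates 1 to 4. Between 78.3% and 84.8% of them lay in the exons of the table. A tested gene had a median of 529 reads per library. In a library of total RNA the mitochondrial ribosomal transcript MT-RNR2 alone took 20.1% to 24.5% of the reads of the denominator, which leaves fewer for other genes.

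Values were compared as log2(RPKM + 0.5). Fold changes are on that scale, which understates the change of genes with low values. Genes entered the test with a mean RPKM of at least 0.5 over the 8 libraries (11375 genes, 10525 of them protein coding). The test was limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on all 8 libraries and without a replicate block. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. On simulated values for the same 11375 genes in 4 against 4 libraries, the test recovered 80.6% of genes changed 1.5-fold, 98.5% of genes changed 2-fold and 100% of genes changed 3-fold. With 200 genes changed it also called 15 unchanged genes, and with none changed it called 0. A further list of 60 genes, raised 1.25-fold, was not counted among either. The simulation drew genes and libraries independently, without the structure that the real libraries share. The recovered shares therefore need not hold for the real data.

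The test, the 21 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The lists were written from background knowledge: androgen response, estrogen response, cell cycle, cell cycle inhibitors, receptors and cofactors, steroid metabolism, targets shared with corticosteroid receptors, apocrine and secretory genes, cholesterol and fatty acid synthesis, unfolded protein response, immediate early genes, interferon response, luminal keratins and adhesion, ribosomal proteins, mitochondrial transcripts, non-polyadenylated RNA, and markers of basal, fibroblast, immune, endothelial and prostate line cells. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move on balance in 1 direction and, in its mixed form, whether they move either way. Adjustment was over the 19 lists with at least 2 tested members. Named genes are the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap, clone and unnamed symbols left out, a fixed panel (ESR1, PGR, FKBP5, ZBTB16, SEC14L2, EAF2, GREB1, TFF1, MYC, CCND1, MYB and another gene that is not reported here), and up to 4 members of each list with the lowest p. Other genes named in the text were picked after their values were seen. Of the listed genes, 3 had no row under their symbol and were not analysed here.

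Alternatives changed the pseudocount, the filter, the scaling between libraries, the treatment labels, the block, the intensity trend, library weights and the libraries included. After the data were examined, limma voom on the recovered reads, voom and median centring each with the block, and 3 covariates (exon share of reads, the same centred within treatment, and the cell cycle mean of each library centred within treatment) were added.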

Results

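The libraries compared E2 alone with E2+DHT in ZR-75-1 cells, 4 per treatment, and ask what an androgen adds to the expression program of estrogen-treated breast cancer cells after 4 h. Depth was 19955045 to 31913885 reads per library for E2 and 19599217 to 34616639 for E2+DHT, and between 18889 and 21937 genes had a value above 0 in a library.

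A small set of genes was higher in the E2+DHT libraries, whose records also give other passages (9 and 11) than those of the E2 libraries (8 and 10). Among protein-coding genes past the threshold, the largest ratios of mean RPKM were in C1orf116, also called specifically androgen-regulated gene, AQP3, a water and glycerol channel, SEC14L2, a lipid-binding protein, and CLDN8, a tight junction protein. Their mean RPKM was 6.56, 4.49, 4.16 and 4.00 times that in E2. FKBP5, a co-chaperone of steroid receptors, rose 2.81 times, and UGDH, which makes the sugar donor for glucuronidation, rose 2.01 times. Only BCL2, an inhibitor of apoptosis, passed as lower, at 0.743 of its level in E2, and it passed in 0 of the 8 fits without single libraries. In total 21 of 11375 tested genes passed the threshold, 20 higher and 1 lower with DHT (limma, Benjamini-Hochberg). The count of lower genes depended on the fit. It was 0 to 1 without single libraries, 4 after median centring and 10 with the replicate number as a block.

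C1orf116 (chromosome 1, 207191866 to 207206101) went from 1.41 ± 0.361 to 9.21 ± 1.99 RPKM (mean ± SD, n = 4 per group), a log2 fold change of 2.35 with a standard error of 0.163 (limma adjusted p = 0.000244). AQP3 (chromosome 9, 33441152 to 33447609) went from 1.74 ± 0.615 to 7.81 ± 1.92 RPKM (log2 fold change 1.90, standard error 0.206, limma adjusted p = 0.00534). CLDN8 (chromosome 21, 31586324 to 31588391) went from 2.35 ± 0.509 to 9.39 ± 2.11 RPKM (log2 fold change 1.79, standard error 0.161, limma adjusted p = 0.00117). SEC14L2 (chromosome 22, 30792846 to 30821305) went from 0.826 ± 0.205 to 3.44 ± 0.620 RPKM (log2 fold change 1.57, standard error 0.131, limma adjusted p = 0.000727). FKBP5 (chromosome 6, 35541362 to 35696360) went from 0.785 ± 0.0897 to 2.20 ± 0.264 RPKM (log2 fold change 1.07, standard error 0.0889, limma adjusted p = 0.000727). UGDH (chromosome 4, 39500375 to 39529931) went from 9.45 ± 0.428 to 19.02 ± 0.969 RPKM (log2 fold change 0.97, standard error 0.0649, limma adjusted p = 0.000244). BCL2 (chromosome 18, 60790579 to 60987361) went from 10.09 ± 0.448 to 7.49 ± 0.245 RPKM (log2 fold change -0.41, standard error 0.0613, limma adjusted p = 0.0337).

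Smaller log2 fold changes passed in HSD11B2, which inactivates cortisol (log2 fold change 0.84), CSRNP1, a nuclear protein (0.83), RGS2, a regulator of G protein signalling (0.76), STEAP2, a metalloreductase (0.69), PARM1, an androgen-regulated mucin-like protein (0.68), and SYBU, which links cargo to kinesin (0.66). Their limma adjusted p lay between 0.0167 for HSD11B2 and 0.0337 for CSRNP1 and RGS2. The 4 values of each of the 21 genes did not overlap between treatments. Of all tested genes 387 (3.4%) did not overlap, against 2.86% by chance, and 508 had an unadjusted p under 0.05, 327 higher and 181 lower.

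**Figure D1:**
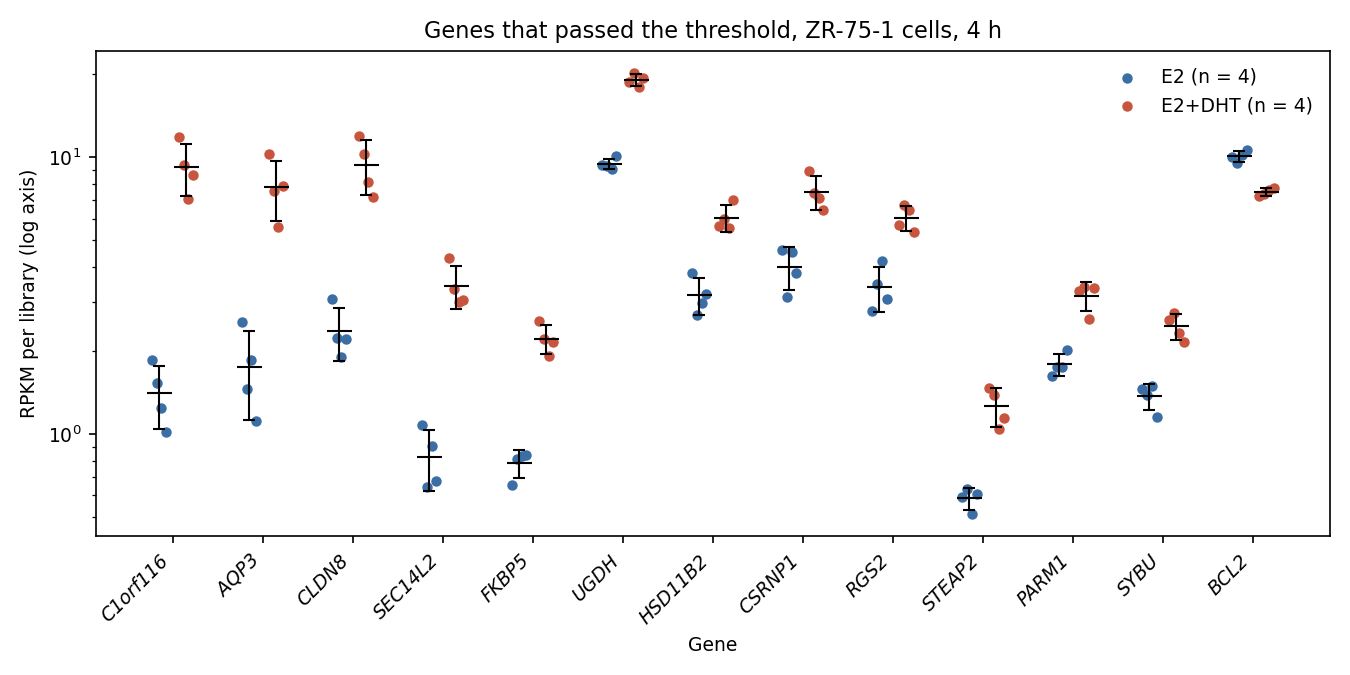
RPKM (y axis, log scale) of the 13 named genes past the threshold (x axis) in each of the 8 libraries, with points for libraries and black bars for the mean ± SD of 4 libraries per treatment. In 12 genes the 4 E2+DHT libraries lie above the 4 E2 libraries, and in BCL2 below them.

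C1orf116, AQP3, CLDN8, SEC14L2, FKBP5 and UGDH passed in each of the 8 fits that left out 1 library, and BCL2 in 0 of 8 (highest limma adjusted p = 0.177). HSD11B2 passed in 5, STEAP2, PARM1 and SYBU in 2, and CSRNP1 and RGS2 in 1 of these fits. The count fell to 18 without E2 replicate 1, to 7, 9 and 6 without E2 replicates 2, 3 and 4, and to 7, 6, 11 and 11 without E2+DHT replicates 1, 2, 3 and 4. With groups taken from the record titles 2 genes passed, neither among the 21. With the replicate number as a block 72 genes passed, including the 21. Some genes given below as not past the threshold then passed (limma adjusted p from 0.00197 for EAF2 to 0.0385 for SLC26A2). They were EAF2, NFKBIA, SLC26A2, ADAMTS1, SERHL2, AKR1C3, PPIF and SPRED2, all higher, and PGR, lower. With all libraries scaled to the same RPKM sum, 18 genes were higher and 4 lower.

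The targets shared with corticosteroid receptors were higher with DHT as a list. Of 15 tested members, FKBP5 and SEC14L2 rose, 0 fell and 13 did not pass. Adjusted over the list alone, 8 rose and 0 fell, the others being NFKBIA, EAF2, PER1, MT2A, ELL2 and KLF9. The members' mean log2 fold change was 0.46 and the median 0.35, and 14 of 15 were positive (limma camera adjusted p = 2.92e-17, and adjusted p = 0.0288 with an estimated correlation, limma fry adjusted p = 0.00698). EAF2, an elongation factor partner, had 2.67 ± 0.334 RPKM in E2 and 5.67 ± 1.53 in E2+DHT (n = 4 per group, limma adjusted p = 0.0789). NFKBIA, the inhibitor of NF-kappa-B, had 21.1 ± 3.15 and 32.01 ± 2.11 RPKM (n = 4 per group, limma adjusted p = 0.0573). Leaving out single libraries, the estimated-correlation call held in 3 of 8 fits. It was lost without E2 replicate 1 (limma camera adjusted p = 0.182) or 3 (0.139) and without E2+DHT replicate 2 (0.0831), 3 (0.0581) or 4 (0.0509). With the replicate block 4 members rose and 0 fell, but this call was lost (limma camera adjusted p = 0.286, limma fry adjusted p = 0.0441). ZBTB16, another shared target, had 1 recovered read over all E2 libraries and 2 over all E2+DHT libraries, too few to compare.

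The androgen response list was taken mostly from prostate lines. Of 84 tested members FKBP5 rose, 0 fell and 83 did not pass. For this list, adjusted over the list alone, 12 rose and 0 fell, among them SLC26A2, a sulfate transporter, ADAMTS1, a secreted protease, TNFAIP8 and SCD, a fatty acid desaturase. Over all genes, SLC26A2 had a log2 fold change of 0.41 (limma adjusted p = 0.0829), ADAMTS1 0.60 (limma adjusted p = 0.120), TNFAIP8 0.31 (limma adjusted p = 0.192) and SCD 0.34 (limma adjusted p = 0.202). The members' mean log2 fold change was 0.10 and the median 0.062, with 55 of 84 positive (limma camera adjusted p = 3.77e-06, and adjusted p = 0.809 with an estimated correlation, limma fry adjusted p = 0.248).

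Of the 18 tested apocrine and secretory genes CLDN8 rose, 0 fell and 17 did not pass, with the same count adjusted over the list alone. The list had a mean log2 fold change of 0.21 and 16 of 18 members positive (limma camera adjusted p = 0.000241, and adjusted p = 0.527 with an estimated correlation, limma fry adjusted p = 0.248). SERHL2 had a log2 fold change of 0.48 (limma adjusted p = 0.453), and its reads may be shared with its near copy SERHL. AZGP1, a secreted glycoprotein, had 80.1 ± 6.37 RPKM in E2 and 92.8 ± 7.77 in E2+DHT (n = 4 per group, limma adjusted p = 0.999). Of the 14 tested steroid metabolism genes HSD11B2 rose, 0 fell and 13 did not pass (limma camera adjusted p = 0.0298, and adjusted p = 0.882 with an estimated correlation, limma fry adjusted p = 0.485). Adjusted over the list alone, 2 rose and 0 fell. The other was AKR1C3, which reduces steroid ketones and has close paralogs, with a log2 fold change of 0.67 (limma adjusted p = 0.120). The steroid metabolism list lost its preset-correlation call in 2 of the 8 fits that left out 1 library, E2 replicate 2 (limma camera adjusted p = 0.0779) and E2+DHT replicate 3 (limma camera adjusted p = 0.141).

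The estrogen response list did not pass as a whole. Of 53 tested members SYBU rose, 0 fell and 52 did not pass (mean log2 fold change 0.036, limma camera adjusted p = 0.705, and adjusted p = 0.942 with an estimated correlation). Members moved when either direction was allowed, with a limma fry mixed-direction adjusted p of 0.00214. This test does not show that they moved apart. For the corticosteroid receptor shared targets, 14 of 15 positive, the limma fry mixed-direction adjusted p was 6.68e-05. Adjusted over the list alone, SYBU, PPIF, SGK3 and TIPARP rose and PGR and KCNK5 fell. PGR, the progesterone receptor and a classic estrogen target, had 5.39 ± 0.982 RPKM in E2 and 3.57 ± 0.282 in E2+DHT (n = 4 per group, limma adjusted p = 0.158). PPIF, a mitochondrial cyclophilin, had 24.8 ± 4.17 and 39.0 ± 4.33 RPKM (n = 4 per group, limma adjusted p = 0.0799). Log2 fold changes were 0.26 for GREB1, -0.092 for TFF1, -0.085 for MYC, -0.14 for CCND1 and -0.18 for MYB, and none of these 5 passed (limma adjusted p from 0.985 to 0.999).

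Among the 26 tested receptors and cofactors 0 rose, 0 fell and 26 did not pass (limma camera adjusted p = 0.802, and adjusted p = 0.942 with an estimated correlation, mixed-direction fry adjusted p = 0.00933). GRHL2 and NCOA1 rose and PGR fell when adjusted over the list alone. ESR1, the estrogen receptor, had 6.82 ± 0.792 RPKM in E2 and 5.52 ± 0.525 in E2+DHT (n = 4 per group, limma adjusted p = 0.761).

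**Figure D2:**
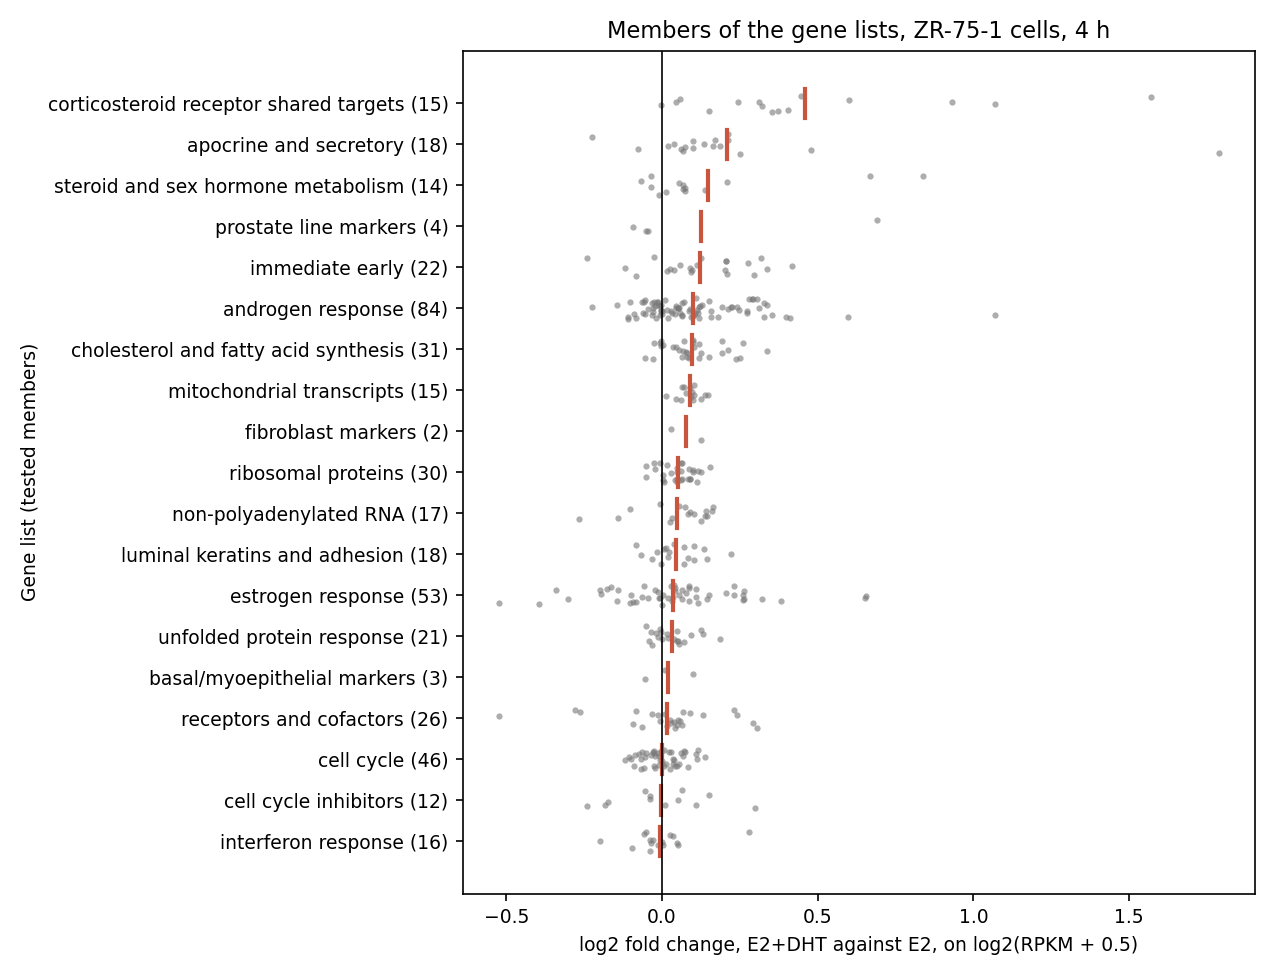
Log2 fold change of E2+DHT against E2 on the log2(RPKM + 0.5) scale (x axis) for each tested member (grey points) of 19 gene lists (y axis, tested members in brackets), with the list mean as a red bar. The corticosteroid receptor shared targets have the highest mean, 0.46, and cell cycle genes lie around 0.

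None of the 46 cell cycle genes passed, over all genes or adjusted over the list alone (mean log2 fold change 0.00058, median -0.0040, limma camera adjusted p = 0.615 in the lower direction, and adjusted p = 0.942 with an estimated correlation). E2F1, a driver of entry into S phase, had 17.8 ± 3.09 RPKM in E2 and 19.1 ± 1.20 in E2+DHT (n = 4 per group, limma adjusted p = 0.999). Cell cycle genes were lower in the replicate 1 libraries. Relative to the other genes, their mean was -0.30 in both replicate 1 libraries and between 0.07 and 0.16 in the other libraries. The list, measured against other genes, therefore moved with single libraries, to -0.12 without E2 replicate 1 (limma camera adjusted p = 0.000403) and to 0.076 without E2+DHT replicate 1 (limma camera adjusted p = 0.0011). Neither call held with an estimated correlation (adjusted p = 0.905 and adjusted p = 0.896 with an estimated correlation, limma fry adjusted p = 0.716 and 0.924). It turned to 0.0020, 0.0061 and 0.030 without E2 replicates 2, 3 and 4. Of 12 tested cell cycle inhibitors 0 passed (limma camera adjusted p = 0.576), over all genes or adjusted over the list alone.

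**Figure D3:**
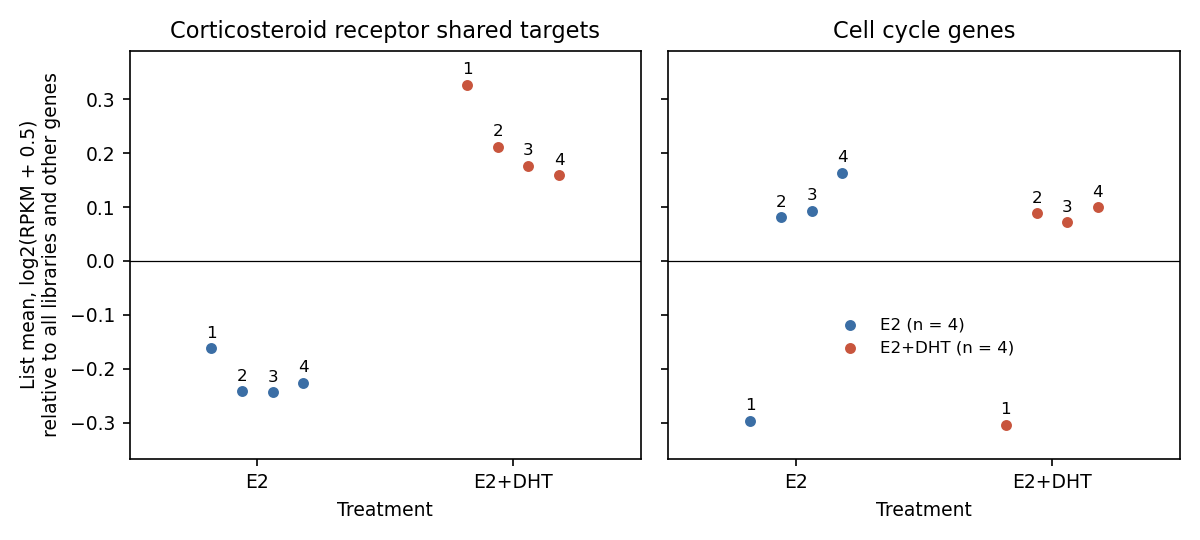
Mean log2(RPKM + 0.5) of 2 gene lists in each library, relative to all libraries and to the other genes (y axis), for E2 and E2+DHT (x axis), with points for libraries and their replicate numbers above them. The corticosteroid receptor shared targets are higher in the 4 E2+DHT libraries than in the 4 E2 libraries, while cell cycle genes are at -0.296 and -0.304 in the replicate 1 libraries and above 0 in the others.

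Of 22 immediate early genes 0 passed, with a mean log2 fold change of 0.12 and 18 positive (limma camera adjusted p = 0.000232, and adjusted p = 0.527 with an estimated correlation, limma fry adjusted p = 0.248). SPRED2, ZFP36 and SPRED1 rose and 0 fell when adjusted over the list alone. SPRED2, an inhibitor of MAP kinase signalling, had a log2 fold change of 0.42 (limma adjusted p = 0.0829). ZFP36, which destabilises mRNAs, had 0.34 (limma adjusted p = 0.212). Of 31 cholesterol and fatty acid synthesis genes 0 passed and 25 were positive (limma camera adjusted p = 0.00133, and adjusted p = 0.882 with an estimated correlation, limma fry adjusted p = 0.552), and SCD rose over the list alone. ACACA, the rate-limiting enzyme of fatty acid synthesis, had 8.96 ± 0.924 and 10.4 ± 0.412 RPKM (n = 4 per group, limma adjusted p = 0.985).

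The remaining lists did not pass, and 0 of their members passed except STEAP2. Limma camera adjusted p was 0.576 for 21 unfolded protein response genes, 0.465 for 16 interferon response genes, 0.667 for 18 luminal keratin and adhesion genes and 0.380 for 30 ribosomal protein genes. It was 0.465 for 15 mitochondrial transcripts and 0.447 for 17 non-polyadenylated RNAs. E2 replicate 2, with the lowest share of reads in exons (78.3%), had the highest mean of mitochondrial transcripts relative to the other genes (0.541, against -0.373 to 0.293 in the other libraries). Without it this list, measured against other genes, went from 0.067 to 0.258 (limma camera adjusted p = 4.93e-09, and adjusted p = 0.267 with an estimated correlation). With exon share as a covariate, whose mean was 81.2% in E2 and 84.0% in E2+DHT with overlapping ranges, it was 0.525 (limma camera adjusted p = 7.67e-26, and adjusted p = 0.0443 with an estimated correlation, limma fry adjusted p = 0.0873). Ribosomal protein genes passed without E2 replicate 1 (limma camera adjusted p = 0.00304, and adjusted p = 0.905 with an estimated correlation) and without E2+DHT replicate 4 (limma camera adjusted p = 0.0217, and adjusted p = 0.954 with an estimated correlation). IFIH1, a sensor of viral RNA, had 5.06 ± 0.206 and 4.36 ± 0.287 RPKM (n = 4 per group, limma adjusted p = 0.765). Adjusted over the list alone, 0 members of these 6 lists passed. Markers of other cell types were low. Of the immune and endothelial markers 0 reached the minimum level, the highest being LYZ at 0.440 and VWF at 0.0817 RPKM. Of 14 basal markers 3 and of 14 fibroblast markers 2 were tested, and 0 passed (limma camera adjusted p = 0.936 and 0.465). Of 14 prostate line markers 4 were tested and STEAP2 rose, also adjusted over the list alone (mean log2 fold change 0.13, median -0.049, limma camera adjusted p = 0.465).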

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

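No test in this part was chosen after its result was seen. In 90 groups of 4 libraries, the values of 39 of the named genes and of library measures such as depth and exon share in each treatment, 4 had a library far from the other 3, its gap to the nearest being over Dixon's critical share of the whole range. About 1 in 20 groups does so by chance. FKBP5 in E2 was 0.652 RPKM in replicate 1, against 0.813 to 0.841 in the other libraries. SCD in E2 was 162.9 RPKM in replicate 3, against 144.6 to 146.3. PARM1 in E2+DHT was 2.60 RPKM in replicate 3, against 3.28 to 3.40. PPIF in E2+DHT was 45.4 RPKM in replicate 1, against 36.1 to 37.7.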

How the results depend on the processing

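The voom fits, the covariates, median centring with the block and the test of exon share were chosen after seeing the data. Of 21 genes past the threshold (20 higher, 1 lower), all kept their direction where tested under every alternative except the grouping by record titles, where 4 did. That grouping sets replicates 1 and 2 of both treatments against 3 and 4. Counts of genes past the threshold (higher, lower) were 20 (19, 1) with a pseudocount of 0.1, 21 (20, 1) with a pseudocount of 1, 21 (20, 1) without the intensity trend and 15 (14, 1) with a mean RPKM of at least 2. They were 22 (18, 4) after scaling to the same sum, 33 (29, 4) after median centring, 30 (26, 4) after quantile normalization, 47 (42, 5) with array weights and 22 (20, 2) with voom on recovered reads, which shared 18 of the 21. The count was 5 (5, 0) with no filter, where 27594 genes share the adjustment, and 5 (5, 0) with exon share as a covariate, whose mean differs between treatments while its ranges overlap. With exon share centred within treatment it was 36 (33, 3) and with the cell cycle mean centred within treatment 26 (25, 1). It was 2 (2, 0) with groups from the record titles and 0 with the 4 records whose labels agree (limma; 286 at an unadjusted p under 0.05), where fewer samples remain. With a fold of at least 1.5 as well, 0 lower genes remained. The cause was not tested otherwise.

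Libraries of 1 number were not paired, which the labels leave open. Their passages differ record by record but match by the titles' numbers. Deviations from the group means correlated at 0.703, 0.455, 0.121 and 0.083 for replicates 1 to 4. Not every library correlated best with its own number, E2 replicate 4 doing so with E2+DHT replicate 2 (0.329) and E2+DHT replicate 3 with E2 replicate 4 (0.216), a hint from the data only. With the replicate block 72 genes passed (62 higher, 10 lower), including the 21, with voom and the block 173 (112, 61), and with median centring and the block 131 (107, 24). In the 8 splits that part all 4 numbers the real one gave 72 and the highest other 1 (1 of 8 gave as many), too few splits for a share under 0.05. The cell cycle mean as a covariate gave 26 genes, which argues against it as the main cause of the gain with the block, and exon share gave 36, so it may account for part. Leaving out single libraries gave 6 to 18 genes, 6 to 18 of them higher and 0 to 1 lower.

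List values here are the members' mean log2 fold change minus that of the other tested genes. The androgen response list was 0.080 and kept its direction in all alternatives and its preset-correlation call in all but the record titles, where it was 0.0049 (limma camera adjusted p = 0.742). With an estimated correlation it passed in none (adjusted p = 0.809 with an estimated correlation as reported, and from 0.1065 to 0.989 over the alternatives). Without single libraries it ranged from 0.0659 to 0.0849. The estrogen response list, 0.014, passed in none, and turned to -0.0015 with a mean RPKM of at least 2, to -0.0043 with record titles and to -0.018 with array weights, with a range of 0.0017 to 0.0296 without single libraries. The cell cycle list, -0.021, was 0.215 with record titles (limma camera adjusted p = 3.95e-24), 0.193 with the 4 agreeing records (limma camera adjusted p = 3.45e-13), 0.0594 with exon share as a covariate (limma camera adjusted p = 0.0391), and from -0.124 to 0.0763 without single libraries. None of these 3 calls held with an estimated correlation (adjusted p = 0.626, 0.688 and 0.720). Of the other lists with a call, the corticosteroid receptor shared targets kept the preset-correlation call except with record titles (limma camera adjusted p = 0.228). With an estimated correlation they did not pass with record titles (adjusted p = 0.982), the 4 agreeing records (0.688), a mean RPKM of at least 2 (0.0689), array weights (0.0661), exon share (0.0605) or the cell cycle mean (0.0568) centred within treatment, and the block (0.286), alone or with voom (0.1125) or median centring (0.0562). With record titles immediate early (limma camera adjusted p = 0.742), cholesterol and fatty acid synthesis (0.895) and steroid metabolism genes (0.147) lost the preset-correlation call and apocrine genes reversed to -0.0933 (limma camera adjusted p = 0.00802, and adjusted p = 0.982 with an estimated correlation). Steroid metabolism lost its preset-correlation call with a mean RPKM of at least 2 (limma camera adjusted p = 0.293), and apocrine genes with the 4 agreeing records (limma camera adjusted p = 0.499). With exon share as a covariate, steroid metabolism (limma camera adjusted p = 0.520) and cholesterol and fatty acid synthesis (limma camera adjusted p = 0.695) lost it. With record titles both replicate 1 libraries, low in cell cycle genes, fall on 1 side. Preset calls were gained by ribosomal proteins, lower with record titles (-0.094, limma camera adjusted p = 8.53e-06), the 4 agreeing records (-0.066, 0.0499) and exon share (-0.072, 0.0107) but higher with array weights (0.061, 0.017), and by luminal genes, higher with both label alternatives (0.084, 0.00802 and 0.108, 0.0499), none with an estimated correlation (lowest adjusted p = 0.720).

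With groups from the record titles, log2 fold changes turned to -0.42 for C1orf116, -0.35 for AQP3, -0.40 for CLDN8, -0.18 for SEC14L2, -0.029 for FKBP5, -0.013 for UGDH, -0.064 for CSRNP1, -0.17 for STEAP2, -0.012 for PARM1, -0.14 for SYBU and 0.079 for BCL2. They turned to 0.069 for ESR1, -0.38 for EAF2, -0.11 for GREB1, 0.055 for TFF1, 0.22 for CCND1, -0.046 for SLC26A2, -0.20 for ADAMTS1, -0.025 for SERHL2, -0.12 for PPIF and -0.086 for SGK3. They turned to -0.056 for ZFP36, -0.053 for GRHL2, -0.014 for NCOA1, -0.20 for AKR1C3 and 0.0049 for IFIH1. None of these passed, their limma adjusted p lying between 0.969 and 1. CCND1 was 0.077 with the 4 agreeing records and E2F1 -0.056 with exon share as a covariate. Depth limits the genes under the minimum of 0.5 RPKM, where 3648 genes with at least 40 reads in all were not tested.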

Other observations

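The bounds for the counts of called genes over the splits, and the tests of the record titles, of scaling and of cell type markers, were chosen only after the results were seen, as were the genes below the expression minimum and the 14 genes named here.

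Below the minimum of 0.5 RPKM, several genes had few reads in E2 and many in E2+DHT. UGT2B28 (chromosome 4, 70146217 to 70160768), which glucuronidates androgens, had 2 reads over the E2 libraries and 59 over the E2+DHT libraries, 23.9 times as many at equal depth (95% exact binomial interval 6.34 to 202.2). UGT2B11 (chromosome 4, 70065669 to 70080449), its close relative, had 4 and 52 reads (10.5 times, 3.88 to 40.2), and how reads that match both near copies were counted is not given. PNMT, which makes adrenaline, had 4 and 39 reads (7.91 times, 2.85 to 30.5), RANBP3L 53 and 298 (4.56 times, 3.40 to 6.23) and C17orf77 18 and 97 (4.37 times, 2.63 to 7.68). The intervals cover counting error only. In the fit without a filter none of these 5 passed, with a limma adjusted p of 0.0512 for UGT2B28, 0.235 for UGT2B11, 0.1 for PNMT, 0.330 for RANBP3L and 0.315 for C17orf77. Of 3648 such genes with at least 40 reads, 65 were higher and 64 lower with DHT without overlap, 3.54% against 2.86% by chance.

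The 21 genes past the threshold were compared with all 35 splits of the 8 libraries into 4 and 4. The real split was the only 1 of 35 with as many genes (21, against at most 2 in any other, the split of the record titles). It was also the only 1 for higher genes (20 against 2), which are 20 of the same 21. This share of 0.0286 is the lowest that 35 splits can give. It speaks against chance only as far as libraries are exchangeable, which the cell cycle difference of the replicate 1 libraries leaves open. Of the 8 splits that part all 4 replicate numbers, fitted with the block, 1 gave as many genes, too few splits to tell. The real split was also the only 1 of 35 with a lower gene (1 against 0), but this is BCL2, which passed in 0 of 8 fits without single libraries (highest limma adjusted p = 0.177), so nothing is concluded from it. That 20 of 21 were higher could come from scaling between libraries. However, 87.9% were still higher after median centring, 86.7% after quantile normalization and 81.8% with the same RPKM sum, which argues against it as the whole cause. With voom and the block 64.7% were higher, so the share depends on the fit. If the record titles and not the library names gave the treatment, the titles should call at least as many genes, but they called 2, and FKBP5, a gene of the fixed panel, was at 0.652 to 0.841 RPKM in the E2 and 1.911 to 2.55 in the E2+DHT libraries of the library names, which argues against the titles. An effect of DHT stays the open biological explanation. Read record by record, a steady trend with passage would put passage 9 between passages 8 and 10. However, the values of none of the 21 genes overlapped between treatments. FKBP5 was at 0.652 and 0.835 RPKM in passage 8, 2.55 and 1.911 in passage 9 and 0.813 and 0.841 in passage 10. For these 21 genes, which were called in this same comparison, this argues against a steady trend. Any other difference in passage, which falls with the library names, cannot be told apart from an effect of DHT.

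The same 35 splits were run for the lists, with camera at its preset correlation. In this exact permutation of the libraries, the androgen response list (limma camera p = 3.96e-07, against 2.1e-05 in the best other split), the corticosteroid receptor shared targets (p = 1.54e-18 against 9.33e-09), apocrine genes (p = 5.07e-05 against 0.000181) and immediate early genes (p = 3.66e-05 against 0.000169) had their lowest p in the real split, 1 of 35, which is the lowest share 35 splits can give. Under the same assumption each of these lists taken alone had a share of 0.0286. After adjustment over the 8 lists the share was 0.0571, so chance is not excluded. Besides the androgen response, estrogen response and cell cycle lists, the 8 were those with a preset-correlation call in the same data. An adjustment over these 8 is therefore too mild. With an estimated correlation only the corticosteroid receptor shared targets passed in the fit as reported (limma camera adjusted p = 0.0288, fry 0.00698). In that fit the androgen response (adjusted p = 0.809 with an estimated correlation), apocrine (0.527) and immediate early lists (0.527) did not pass, nor with fry (0.248 each). In the same exact permutation, for cholesterol and fatty acid synthesis (limma camera p = 0.00035 against 0.000114) and steroid metabolism (p = 0.00942 against 0.0069) 2 of 35 splits gave a p as low, so chance cannot be excluded. By that exact permutation the estrogen response list (26 of 35, limma camera p = 0.631 against 0.00162) and the cell cycle list (27 of 35, p = 0.486 against 4.64e-28) were not separated by treatment. The cell cycle p of 4.64e-28 came from a split with both replicate 1 libraries on 1 side, which points to a structure of the samples other than treatment.

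In E2 replicate 4, 14 genes with at least 20 reads were at least 4 times higher than in each other library, against at most 1 in any other library. They were SERPINA6 (6.73 RPKM against at most 1.05 elsewhere), the replication histones HIST1H2BH, HIST1H3F, HIST1H1D and HIST1H4D, OLFML3 (2.11 against 0.191), GNG11, LIN28A, ELF5, SPINK5, MGST1, PGLYRP2, NLRP2 and SATB1. Cells of another type in the culture could bring such genes, but 0 of the 61 markers of the 5 cell type lists were 4 times higher there, which argues against those types. A general gain of non-polyadenylated RNA could raise histone transcripts, but the fixed list of such RNAs had a median of -0.08 log2 against the other libraries, which argues against it. A type outside the lists was not tested, and no biological explanation was tested within a treatment.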
